A study of Mus musculus with 10 samples.

How the data were processed

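RNA was measured in 10 libraries, each made from the sorted GFP-positive cells of a single mouse embryo at embryonic day 10.5, with 5 embryos per genotype. Per the labels' protocols, embryos were dissociated with trypsin, dead cells were marked with the viability dye 7AAD, and libraries were prepared with a TruSeq RNA kit from polyadenylated RNA on a mixed 129/Sv and C57BL/6 background. The authors deposited raw counts per Ensembl gene, 1 column per library, and the columns were matched to the samples by the sample numbers in the labels. The submitters' processing notes name HISAT2 2.0.4, SAMtools 1.3.1, HTSeq 0.6.1 and DESeq2 1.14.1 with the build GRCm38, without saying what each was used for. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping and antisense genes cannot be told apart and are treated as uncertain. A second table holds the authors' own comparison. Per the file headers it gives a mean normalized count per gene (a signal over all libraries), a log2 fold change with its standard error, a Wald statistic (a score), and an unadjusted and adjusted p-value.

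Counts were analysed as deposited. The table listed 49671 genes, 27213 of them with a count in any library, and no row without a gene name entered the totals. Library totals of 12368058 to 28379562 counts set the depth. Genes were kept by the edgeR function filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14528. Libraries were scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 with robust dispersions in R 4.3.3, with all 10 libraries and no covariate, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each adjusted p given for a gene is from this test unless another is named. The standard error of a log2 fold change was the fold change divided by the square root of the F statistic. CPM are TMM-scaled and given as mean ± SD over the 5 embryos of a group, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 25.5%. Counts were simulated for this comparison of 14528 genes, with 200 genes changed, all drawn from those with a control mean over 2 CPM. Of these, 34.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold were recovered. There were 11 false calls among 141. Recovery of genes with a lower control mean was not simulated.

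The comparison, its tests, 20 gene lists and the rule for naming genes were chosen before the data were examined. The rule names Trp53, Cdkn1a, Mdm2, Chd7 and Tcof1. It also names the 12 largest rises and 12 largest falls with an adjusted p under 0.05, a mean log2 CPM over 1 and no overlap between the groups, leaving out predicted genes. It further names the 5 genes with the smallest p, up to 5 members of each list with the smallest p and any member needed to say that it did not pass. Other genes, such as Wrap53, Isl1, Ccnf and Lin28a, were named after their values were seen. A few tested genes that the rule or a later choice had named are not reported here; they count in the list tests but not in the tallies over named genes or picked values. Lists were tested with camera of limma 3.58.1 at a correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. A further 9 lists were chosen after the data were seen and are reported only in the closing section. Gene positions, exon lengths and overlaps are from GENCODE M21 on GRCm38, in which 49412 (99.5%) of the gene identifiers were found. The ratio given for Ltb4r2 has a 95% interval that covers counting error only. Embryo sex was read from Xist and Y-linked genes.

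The alternatives tried were other scaling (RLE, upper quartile, total counts), other filters, limma-voom, DESeq2 1.42.0, non-robust dispersions, stricter thresholds, embryo sex or the replicate number as a term, the removal of sex-linked and haemoglobin genes, and leaving out each library in turn. Added after the data were seen were the ratio of embryonic globins or an epithelial marker score as a covariate, removal of a lowess trend on gene length (span 0.3), and fits without control replicates 1 and 2 or without p53_activated replicates 4 and 5.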

Results

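Neural crest cells were collected by flow sorting from single mouse embryos at embryonic day 10.5, and polyadenylated RNA of the sorted cells was sequenced, with 1 library per embryo. The sorted cells carried green fluorescent protein switched on by Wnt1-Cre, a recombinase made in the dorsal neural tube, which gives rise to the neural crest. The marked cells can therefore include neural tube cells beside neural crest. In 5 embryos, called p53_activated here, the same recombinase also released a stabilised form of the transcription factor p53 from an engineered Trp53 allele, carried beside a normal allele. The 5 control embryos were littermate controls with normal Trp53. Library totals ran from 12368058 to 23514828 counts in the control group and from 14644162 to 28379562 in the p53_activated group, over 49671 listed genes, of which 14528 had enough counts to be tested. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 16.1 to 87.5). Pearson correlations of log2 CPM, taken across genes, were 0.947 to 0.979 within groups and 0.934 to 0.963 between them. The first principal component, with 32.7% of the variance of the 500 most variable genes, held the control libraries between -22.16 and -12.35 and the p53_activated libraries between 9.59 and 24.02. By Xist and Y-linked transcripts, 2 of the control and 3 of the p53_activated embryos were female.

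The comparison asks how a stabilised p53 changes the transcriptome of neural crest cells, and the engineered gene and its best known targets were read first as a check of the labels. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 7.93 ± 1.59 CPM in control to 105 ± 11.9 CPM in p53_activated libraries (SD, n = 5 each), a log2 fold change of 3.73 ± 0.14 (SE; edgeR quasi-likelihood adjusted p = 1.74e-10). Mdm2, the ubiquitin ligase that limits p53, rose from 24.5 ± 1.06 to 47.3 ± 4.41 CPM, a log2 fold change of 0.95 ± 0.10 (adjusted p = 2.48e-05). For both genes every p53_activated embryo lay above every control embryo. Trp53 itself rose 1.6-fold, from 18.2 ± 5.12 to 29.1 ± 2.99 CPM (log2 fold change 0.67 ± 0.17, adjusted p = 0.0264). That call was lost without control replicate 2 (adjusted p = 0.0716), control replicate 3 (0.0569) or p53_activated replicate 4 (0.0558). Trp53 checks the labels only in part, since the engineered allele is transcribed from the same locus. The pseudogene Trp53-ps was listed at 0 counts in every library. On GRCm38, Trp53 (ENSMUSG00000059552) lies on chromosome 11 from 69580359 to 69591873, Cdkn1a (ENSMUSG00000023067) on chromosome 17 from 29090976 to 29100727 and Mdm2 (ENSMUSG00000020184) on chromosome 10 from 117688875 to 117710758. Wrap53, the neighbour of Trp53, also rose (log2 fold change 0.86 ± 0.11, adjusted p = 9.81e-05). Chd7 and Tcof1, genes whose mutation causes craniofacial disorders, did not pass the test, with log2 fold changes of 0.17 ± 0.12 (adjusted p = 0.467) and 0.22 ± 0.36 (adjusted p = 0.78).

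**Figure D1:**
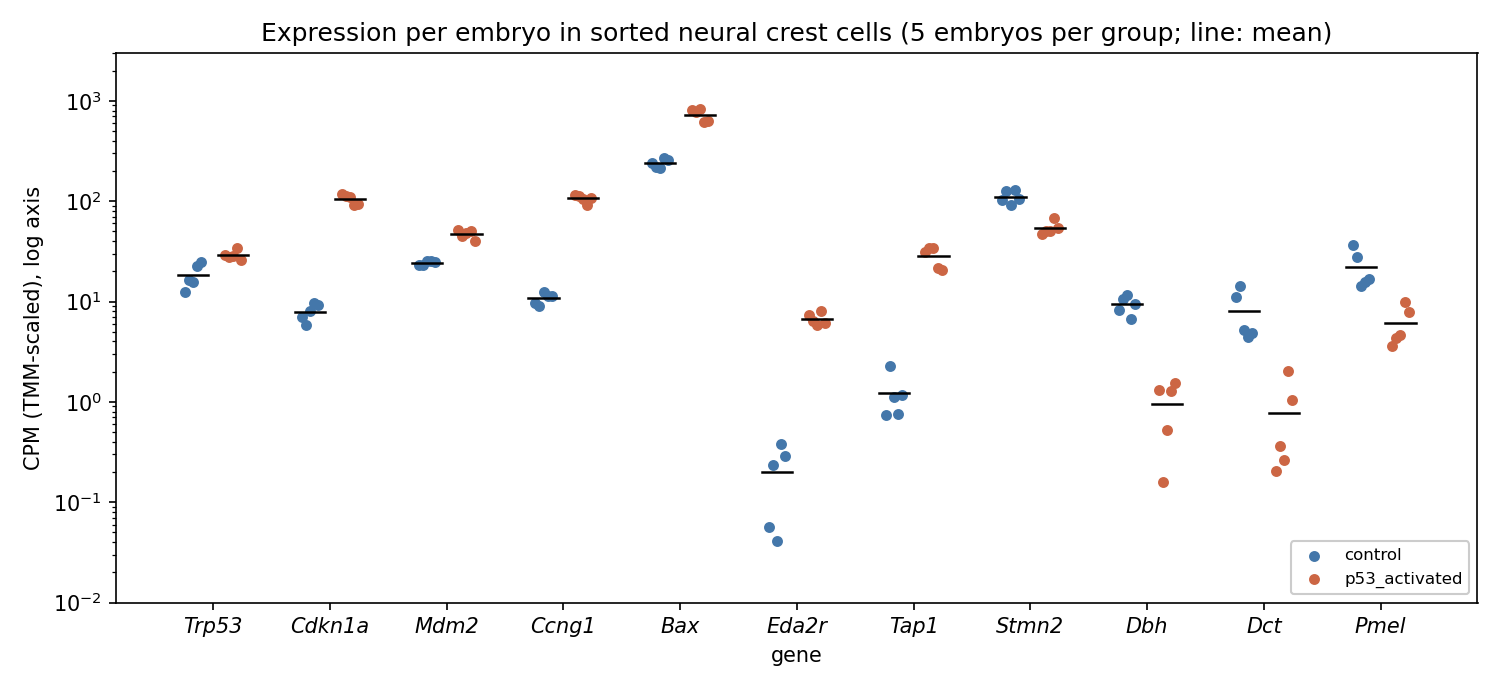
TMM-scaled CPM on a log axis for 11 genes, each point being 1 embryo (5 control, 5 p53_activated) and each line a group mean. Cdkn1a, Ccng1, Bax, Eda2r and Tap1 lie higher in every p53_activated embryo than in any control embryo, and Stmn2, Dbh, Dct and Pmel lie lower in every one.

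Across the transcriptome the largest increases included p53 target genes. Ccng1, a p53 target encoding cyclin G1, had the smallest p of all genes and rose from 10.8 ± 1.42 to 107 ± 8.92 CPM (log2 fold change 3.30 ± 0.12, edgeR adjusted p = 8.12e-11). Next after Ccng1 and Cdkn1a came the adenylate kinase gene Ak1 (2.83 ± 0.12), the DNA repair gene Mgmt (2.65 ± 0.13) and the xylulose reductase gene Dcxr (3.06 ± 0.14), with adjusted p from 3.09e-10 to 2.19e-09. Among the 12 largest rises were a pair of adjacent leukotriene B4 receptor genes on chromosome 14. Ltb4r1 (55765962 to 55768494) rose from 0.322 ± 0.297 to 34.2 ± 6.49 CPM, a log2 fold change of 6.73 ± 0.39. Ltb4r2 (55761428 to 55765138) had 2 counts over all control libraries against 1140 over the p53_activated libraries, a ratio of 510 after scaling for library size, with a 95% counting interval of 141 to 4220. The other rises of this rule were in Ano3 (log2 fold change 5.22 ± 0.37), the ectodysplasin receptor gene Eda2r (5.13 ± 0.43), the carboxypeptidase gene Cpz (4.98 ± 0.26), the peptide transporter gene Tap1 (4.58 ± 0.28), the death receptor gene Fas (3.96 ± 0.61), Def6 (3.86 ± 0.20), Klhdc7a (3.84 ± 0.37), Cdkn1a, the phosphatase gene Ptprv (3.71 ± 0.35) and the taste receptor gene Tas1r1, which went from 0.321 to 8.12 CPM. Fas had the largest adjusted p of the 12 (0.00133). Def6 shares 14.56% of its exon length with another gene, so its count is uncertain.

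The largest decreases included Dbh, Dct and Pmel. Dbh, the enzyme that turns dopamine into noradrenaline, fell from 9.36 ± 1.92 to 0.96 ± 0.588 CPM (log2 fold change -3.28 ± 0.40, edgeR adjusted p = 9.97e-05). Dct and Pmel, which act in pigment synthesis and melanosomes, fell by 3.24 ± 0.59 (adjusted p = 0.00549) and 1.85 ± 0.33 (adjusted p = 0.00517) on the log2 scale. The fall of Dct was 4.08 without p53_activated replicate 4, which held 62 of its 91 counts in p53_activated libraries. The remaining falls of the rule were in Evx1 (-1.78), Zcchc12 (-1.76), Mrln (-1.73), Rgs17 (-1.72), Rgs4 (-1.70), Spem1 (-1.54), Cyb561 (-1.49), Klhdc8a (-1.45) and Sfrp5 (-1.41). Evx1 is a homeobox gene, Rgs4 and Rgs17 encode regulators of G protein signalling, Cyb561 a cytochrome of catecholamine granules and Sfrp5 a secreted Wnt inhibitor. The call of Rgs17 (adjusted p = 0.0463) was lost without each library other than control replicate 5 and p53_activated replicates 1 and 2 (up to 0.112). Mrln lost its call without control replicate 1 (0.0721), control replicate 4 (0.0543) or p53_activated replicate 3 (0.0622), and Spem1 without control replicate 1 (0.0523), control replicate 2 (0.0879) or p53_activated replicate 2 (0.0556).

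In total 1050 genes passed an edgeR adjusted p of 0.05, of which 652 were higher and 398 lower in p53_activated embryos. With a fold change of at least 2 there were 247 higher and 87 lower. Among the called genes 491 of the higher and 304 of the lower had no overlap between the embryos of the groups, as had 1172 (8.07%) of all tested genes, where chance gives 0.794%. The share of higher calls was 62.1%, and 51.7% with upper quartile scaling. The count of calls was 636 without control replicate 2, 692 without control replicate 4 and 652 without p53_activated replicate 5. The higher calls numbered 430 without p53_activated replicate 5, and the lower calls 192, 255, 230, 226 and 222 without control replicates 2 and 4 and p53_activated replicates 2, 3 and 5.

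The 3 lists of p53 target genes were raised as groups. Of 20 targets acting in cell cycle arrest and feedback, 14 rose and none fell (15 rose adjusted over the list alone), with a median log2 fold change of 1.18. Beside Cdkn1a and Ccng1 the rises included Phlda3 (2.37 ± 0.12), Zmat3 (2.30 ± 0.12) and Psrc1 (2.21 ± 0.12), while Gadd45a (-0.05 ± 0.29) and Sesn1 (-0.30 ± 0.15) did not pass. Of 14 apoptosis targets 11 rose and none fell, the same numbers adjusted over the list alone, with a median of 1.51. Bax, which permeabilises mitochondria, rose from 240 ± 24.4 to 730 ± 102 CPM (log2 fold change 1.61 ± 0.11, edgeR adjusted p = 7.11e-08), although 12.18% of its exon length is shared with another gene. Rises were also seen in Tnfrsf10b (2.25 ± 0.18), Pidd1 (1.83 ± 0.13), Aen (1.77 ± 0.13) and Apaf1 (1.49 ± 0.11), whereas Perp (0.29 ± 0.77) did not pass. Of 14 tested targets in DNA repair and metabolism 9 rose and none fell (10 rose adjusted over the list alone), with a median of 1.70. The thiamine transporter gene Slc19a2 (2.83 ± 0.21) was among the rises, and the nucleotide excision repair gene Xpc (-0.03 ± 0.13) did not pass. Gene set tests (camera, correlation 0.01) gave adjusted p of 2.29e-18, 1.62e-17 and 3.4e-13 for the 3 lists, and the calls held with an estimated correlation (adjusted p = 0.00109, 0.00304 and 0.00304).

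Markers of differentiating neurons, glia and melanoblasts were lower in p53_activated embryos. Of 23 tested sensory and autonomic neuron genes 11 fell and none rose (17 fell adjusted over the list alone), with a median log2 fold change of -0.79 (camera adjusted p = 1.51e-12; adjusted p = 0.0173 with an estimated correlation). Stmn2, a microtubule regulator of growing axons, fell from 111 ± 15.7 to 54.2 ± 8.37 CPM (log2 fold change -1.03 ± 0.12, edgeR adjusted p = 4.65e-05), and the neuronal genes Elavl4 (-0.88 ± 0.13) and Tubb3 (-0.77 ± 0.13) fell as well. Falls were also seen in the sensory regulators Pou4f1 (-0.87 ± 0.15) and Isl1 (-1.13 ± 0.21). Th, a catecholamine enzyme gene, did not pass (-1.12 ± 0.38, adjusted p = 0.0905). Of 8 tested glial and melanoblast genes 4 fell and none rose (5 fell adjusted over the list alone), with a median of -1.07 (camera adjusted p = 5.58e-07; adjusted p = 0.0256 with an estimated correlation). Besides Dct and Pmel these included Fabp7 (-0.78 ± 0.16, adjusted p = 0.00767), a gene of glial precursors. Mitf (-1.03 ± 0.52, adjusted p = 0.258) and Kit (-0.20 ± 0.18, adjusted p = 0.555), which melanoblasts require, did not pass.

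Over the 31 members of both lists, the mean log2 CPM, centred on the mean of all libraries, lay between 0.37 and 0.70 in the control libraries, between -0.72 and -0.43 in 4 p53_activated libraries and at -0.02 in p53_activated replicate 4. Median log2 fold changes were also below 0 over 12 epithelial genes (-0.79) and 12 cardiac, skeletal muscle and somite genes (-0.70). Control replicates 1 and 2 had the highest ratios of the embryonic globins Hbb-y and Hbb-bh1 (4.97 and 2.69, against 1.59 to 2.08 in the other 8 libraries) and the lowest Lin28a (2.96 and 6.21 CPM, against 10.8 to 24.8). Without both of these libraries, a choice made after the data were seen, 12 of the 31 markers were called lower, against 15 with all libraries, and all called genes numbered 656.

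**Figure D2:**
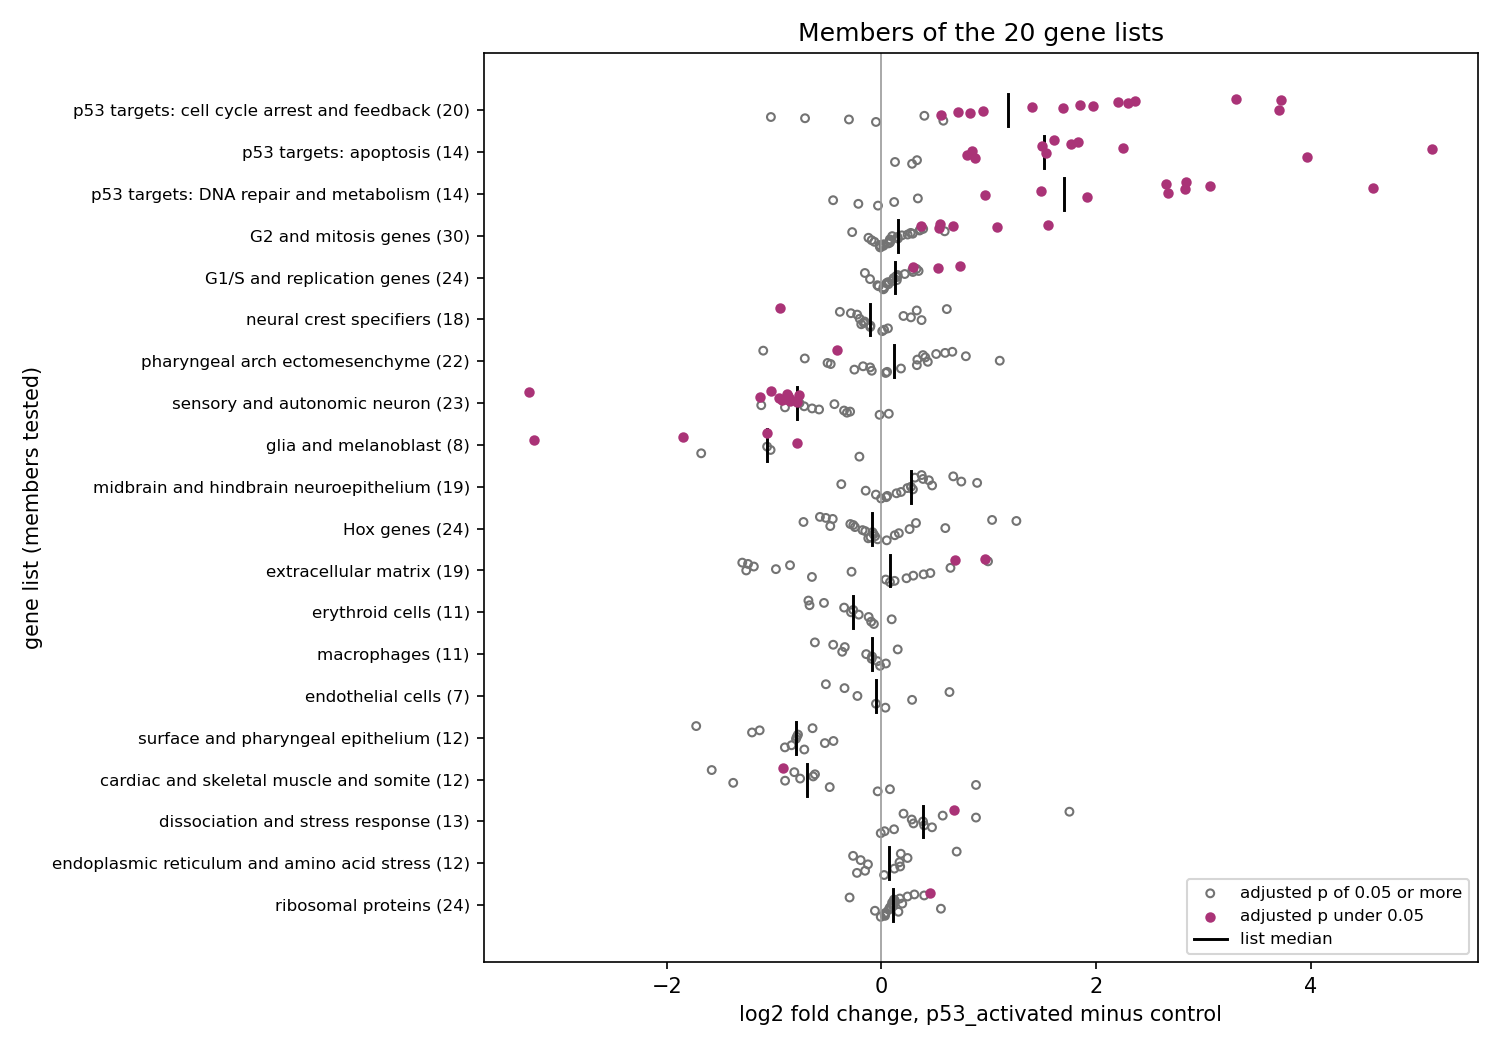
Log2 fold change (p53_activated minus control, x axis) of each tested member of the 20 gene lists (y axis, members tested in brackets), filled where the edgeR adjusted p is under 0.05, with a line at each list median. The 3 p53 target lists have medians of 1.18, 1.51 and 1.70, and the neuron list and the glia and melanoblast list have medians of -0.79 and -1.07.

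No member of the cell cycle lists fell. Of 30 G2 and mitosis genes 6 rose (10 adjusted over the list alone), with a median log2 fold change of 0.15. They were the kinetochore genes Cenpf (0.55 ± 0.10, edgeR adjusted p = 0.0039) and Cenpe (0.37 ± 0.08), the spindle genes Kif20a (1.55 ± 0.30), Hmmr (0.66 ± 0.17) and Prc1 (1.08 ± 0.28), and the cyclin F gene Ccnf (0.54 ± 0.14). Kif20a shares 29.3% and Prc1 11.08% of its exon length with a neighbouring gene, so their counts are uncertain. Cdk1 (-0.01 ± 0.21), Ccnb1 (-0.01 ± 0.14) and Mki67 (0.10 ± 0.08), genes of dividing cells, did not pass. Of 24 tested G1/S and replication genes 3 rose, the same number adjusted over the list alone, with a median of 0.13: Chaf1a (0.73 ± 0.16), which overlaps Ubxn6 over 52.5% of its exon length, Uhrf1 (0.29 ± 0.08) and Rrm2 (0.53 ± 0.15). The camera calls of the lists (adjusted p = 0.00105 and 0.0142) were lost with an estimated correlation (adjusted p = 0.603 and 0.635), and that of the G1/S list also without control replicate 1 (0.165) or 2 (0.053). Hmmr lost its call without control replicate 3 (0.0512) or p53_activated replicate 4 (0.0517) or 5 (0.0539). Prc1 lost its call without each library but control replicates 2 and 5 and p53_activated replicates 1 and 2 (up to 0.0844), Ccnf without each but control replicates 1, 3 and 5 and p53_activated replicate 4 (up to 0.0761), Uhrf1 without each but control replicates 3 and 5 and p53_activated replicate 4 (up to 0.0968), and Rrm2 without each but control replicate 4 and p53_activated replicates 1 and 2 (up to 0.0992). In fits chosen after the data were seen, Cenpf (0.36, adjusted p = 0.0586), Cenpe (0.27, 0.102) and Ccnf (0.46, 0.108) lost their calls with a trend on gene length removed. Without p53_activated replicates 4 and 5 the calls of Kif20a (1.01, 0.0567), Hmmr (0.55, 0.108), Prc1 (0.61, 0.208), Chaf1a (0.45, 0.09), Uhrf1 (0.30, 0.0752) and Rrm2 (0.47, 0.137) were lost.

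Few genes that define the neural crest and the pharyngeal arch mesenchyme passed the test. Of 18 neural crest specifiers Snai2 fell (-0.94 ± 0.26, edgeR adjusted p = 0.0416) and none rose, with a median log2 fold change of -0.10 (camera adjusted p = 0.762), while Sox10 (-0.10 ± 0.17), Tfap2a (0.01 ± 0.18) and Twist1 (-0.23 ± 0.14) did not pass. Of 22 tested arch genes Prrx2 fell (-0.41 ± 0.11, adjusted p = 0.0386) and none rose, with a median of 0.12 (camera adjusted p = 0.414). Adjusted over the list alone Snai2 was called (1 lower) and Prrx2 was not (0 lower). Gsc did not pass (-1.10 ± 0.31, adjusted p = 0.057) but did under 7 of 26 other settings (0.00146 to 0.0496), among them without control replicate 3 (0.013). Snai2 lost its call without each library but control replicates 3, 4 and 5 and p53_activated replicate 4 (up to 0.102), and Prrx2 without each but control replicates 4 and 5 and p53_activated replicate 1 (up to 0.106). Without both control replicates 1 and 2, a choice made after the data were seen, Snai2 was at -0.41 (adjusted p = 0.269) and Prrx2 at -0.23 (0.196), and over 26 other settings the 2 genes lost their calls in 14 and 13. Of 24 tested Hox genes 0 were called at either adjustment (median -0.09, camera adjusted p = 0.563), with Hoxb5 (-0.57 ± 0.17, adjusted p = 0.055) passing under 3 of 26 other settings, among them without control replicate 3 (0.0341). Without control replicates 1 and 2 the Hox list was called lower (0.0209) and the arch list higher (0.0158). Of 19 tested midbrain and hindbrain neuroepithelium genes 0 were called at either adjustment, among them Otx2 (0.38 ± 0.17) and Wnt1 (0.67 ± 0.29), the latter passing without control replicate 3 (0.00192) and with the replicate block (0.0434). Their median of 0.28 gave a camera adjusted p of 0.0418, against an adjusted p of 0.635 with an estimated correlation and 0.0854, 0.171, 0.0583, 0.128 and 0.109 without control replicates 1, 2 and 4 and p53_activated replicates 3 and 5.

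In the extracellular matrix list Col2a1, a cartilage collagen gene (0.97 ± 0.21, edgeR adjusted p = 0.018), and Vcan, a proteoglycan gene (0.69 ± 0.19, adjusted p = 0.0416), rose among 19 tested (3 higher and 3 lower adjusted over the list alone). The list median (0.08) was above 0 while its mean (-0.15) and test direction were below (camera adjusted p = 0.937). Col2a1 lost its call without control replicate 1 (0.058), and Vcan without each library but control replicates 1 and 2 and p53_activated replicates 1 and 3 (up to 0.09). Postn, Col6a2 and Thbs1 did not pass. Postn and Col6a2 were called lower under 6 and 5 of 26 other settings, among them DESeq2 (adjusted p = 0.0242 and 0.012). Thbs1 was called higher under 5 of the 26, among them DESeq2 (0.0175). Of 24 ribosomal protein genes, whose pseudogenes can share reads with them, Rps19 rose (0.45 ± 0.09, adjusted p = 0.00443; 1 adjusted over the list alone), with a list median of 0.11. The camera adjusted p of 0.0499 became an adjusted p of 0.775 with an estimated correlation and was above 0.05 without each library but control replicates 4 and 5 and p53_activated replicate 4 (up to 0.198). Of 13 dissociation and stress response genes Jun rose (0.68 ± 0.19, adjusted p = 0.0486; 1 adjusted over the list alone), a call lost without each library but control replicate 3 and p53_activated replicate 4 (up to 0.103). Their median of 0.39 gave a camera adjusted p of 0.00861, against 0.0888 without control replicate 2 and an adjusted p of 0.603 with an estimated correlation. Of 12 endoplasmic reticulum and amino acid stress genes 0 were called at either adjustment (median 0.07, camera adjusted p = 0.705).

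Markers of other cell types were read in the same way. All 12 tested epithelial genes had log2 fold changes below 0 and 0 were called at either adjustment, with Epcam at -1.13 ± 0.51 and Krt18 at -0.64 ± 0.27. With the replicate block Epcam (adjusted p = 0.0277), Krt18 (0.0136) and Esrp1 (0.0378) were called lower. Of 12 muscle and somite genes Tnni1, a troponin gene, fell (-0.92 ± 0.25, edgeR adjusted p = 0.039, with 3 lower adjusted over the list alone). That call was lost without each library but control replicate 1 and p53_activated replicates 4 and 5 (up to 0.0969). Myog did not pass but was called lower under 9 of 26 other settings, among them DESeq2 (adjusted p = 0.00903) and the replicate block (0.0423). Actc1 and Myl4 did not pass either, but were called lower under 4 and 1 of the 26. These 2 lists had camera adjusted p of 0.00326 and 0.00484, lost with an estimated correlation (adjusted p = 0.635 and 0.615). Of 11 erythroid, 11 macrophage and 7 endothelial genes 0 were called at either adjustment (medians -0.26, -0.09 and -0.05, the endothelial mean being below 0 and its test direction above; camera adjusted p = 0.222, 0.937 and 0.937). The erythroid list had a camera adjusted p of 0.0187 without control replicate 3 and 0.0111 without p53_activated replicate 4.

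The called genes also differed in length. In the longest eighth of the tested genes by summed exon length 168 of 1814 genes were called higher and 19 lower by edgeR, whereas in the shortest eighth 22 of 1815 were called higher and 60 lower (Fisher's exact test, two-sided, p = 1.24e-30 for the higher and 3.31e-06 for the lower calls). That test counts genes as independent replicates, which they are not, so its p does not measure the spread between embryos. The median log2 fold change was 0.14 in the longest and -0.08 in the shortest eighth. Relative to the mean of all libraries, p53_activated replicate 4 had a median of 0.32 in the longest and -0.19 in the shortest eighth, and p53_activated replicate 5 had 0.13 and -0.02. Without both of these libraries 775 genes were called, and with a trend on gene length removed from each library 962 were called, 826 of them among the 1050, both fits being chosen after the data were seen. With the trend removed the neuron list had 10 lower calls and the glia and melanoblast list 4, while the 3 p53 target lists had 14, 11 and 9 higher calls.

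**Figure D3:**
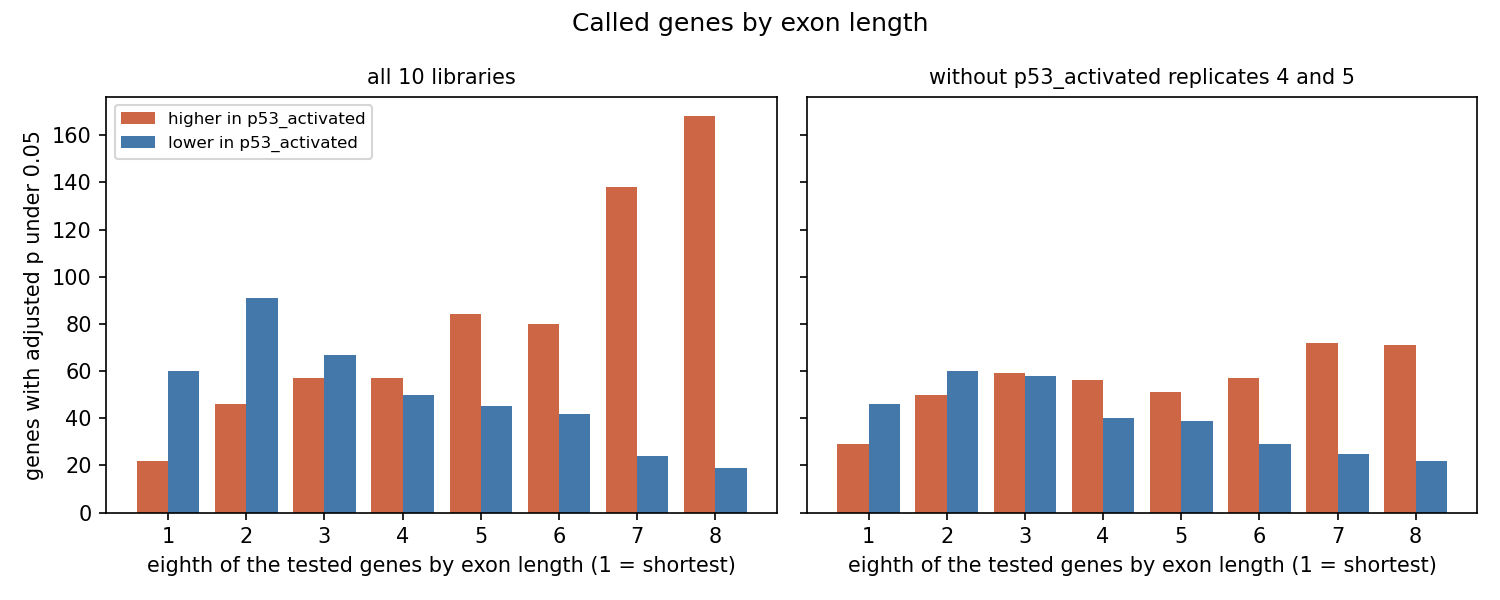
Number of genes with an edgeR adjusted p under 0.05 (y axis) in each eighth of the tested genes by summed exon length (x axis, 1 being the shortest), higher and lower in p53_activated, with all 10 libraries (left) and without p53_activated replicates 4 and 5 (right). Higher calls go from 22 in the shortest to 168 in the longest eighth on the left and from 29 to 71 on the right.

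The authors' deposited table of the same comparison called 1624 genes at its adjusted p under 0.05, 956 higher and 668 lower, of 15089 with an adjusted p. All 1050 genes called here by edgeR were among the calls of the authors' deposited table, in the same direction, and 550 further tested genes were called only in the authors' deposited table. Embryo sex was tested as a modifier of the genotype effect, and the interaction was called for 0 genes (edgeR), with 337 genes at an unadjusted p under 0.05 where 726 would be expected by chance. With sex as a covariate 741 genes were called, 245 of them lower.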

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

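The values in the last paragraph were picked by a rule set before the data were examined. It was applied also to genes named only after their values were seen, such as Ccnf and Axin2. The marker score of p53_activated replicate 4 was not picked by it but noted in the data, and of the tests weighing it, the one on the p53 targets and the one on cells of other lineages were chosen only after the result was seen. Within a group of 5 embryos, a value was picked when its gap to the nearest embryo, divided by the range of the group, was above the 95% limit of Dixon's test. Of 364 such groups 17 met this, 12 with a highest and 5 with a lowest value. Chance gives about 1 in 20, so there was no excess of picked values.

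The neuron, glia and melanoblast markers were least reduced in p53_activated replicate 4, whose mean log2 CPM over them was -0.024 against -0.719 to -0.427 in the other 4 p53_activated libraries. Its p53 targets lay 0.002 above the mean of the other 4 (group difference 1.496). Over the 34 targets called higher it lay 0.126 below them (group difference 2.124), and it was the lowest p53_activated library for 15 of the 34. The mean log2 CPM of the 34 was lower still in p53_activated replicate 5 (5.694, against 5.748 in replicate 4), which was the lowest library for 10. The marker score of p53_activated replicate 5 was -0.427, against -0.719 to -0.56 in p53_activated replicates 1 to 3. The target means of those libraries were 5.913 to 5.954. Replicates 4 and 5 thus had the lowest target means and the highest marker scores, which goes with a weaker response. The target mean of replicate 4 was nonetheless only 0.126 below the others, of a group difference of 2.124. This argues against a p53 response weakened in proportion to the markers, or an admixture of cells of control genotype, as the whole cause. A slightly weaker response stays open. With the gene length trend removed the markers still lay 0.388 above the highest of the others, whose SD was 0.137, which argues against that trend as the whole cause. In 4 of the 5 lists of other lineages (erythroid, macrophage, endothelial, epithelium, muscle and somite) replicate 4 had the highest score of the p53_activated libraries. These lists share no gene with the markers, so they do not tell whether such cells would raise the markers. Among the controls, replicates 4 and 5 had the highest epithelial scores (1.3 and 1.445). Their marker scores were 0.455 and 0.427, against 0.374 to 0.702 over all controls. A mixture with cells of other lineages was therefore neither shown nor excluded, and how far the sort on GFP removed them was not measured here. A difference between embryos in the number of neurons, glia and melanoblasts, or in their expression per cell, was not tested and stays open.

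In that same library Vcan was 146.7 CPM (81.76 to 98.78 in the others of its group), Thbs1 17.55 (5.106 to 8.602) and C1qa, a macrophage gene, 13.8 (3.6 to 6.459), while Ccnb1 was 35.73 (50.57 to 53.15). Control replicate 1 had the highest C1qa of its group at 22.91 CPM (1.578 to 7.431) and the highest Klhdc8a at 16.32 (6.265 to 8.887). It had the lowest Ccnf at 53.39 (77.01 to 83.92), the lowest Axin2 at 7.619 (9.178 to 9.516) and the lowest mean log2 CPM of the G2 and mitosis genes, -0.458 (-0.093 to -0.012). Among the other control embryos, Tap1 was 2.281 CPM in replicate 2 (0.739 to 1.166), Wnt1 40.66 in replicate 3 (12.27 to 19.27), Rrm2 177.7 in replicate 4 (114.5 to 129.1) and Hoxb2 1.457 in replicate 5 (up to 0.787). Among the other p53_activated embryos, Klhdc7a was 10.08 CPM in replicate 2 (5.466 to 6.546) and Tnfrsf10b 68.67 in replicate 3 (46.16 to 51.41). The mean log2 CPM of the stress response genes was highest in p53_activated replicate 1 (0.527, against 0.218 to 0.297), and that of the apoptosis targets was lowest in p53_activated replicate 5 (0.613, against 0.834 to 0.911).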

How the results depend on the processing

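The fits with the globin ratio, the epithelial score, the gene length trend or pairs of libraries left out were chosen only after the data were seen, and the others before. The 3 p53 target lists and the neuron and glia and melanoblast lists were called in the same direction under each of 22 settings, with adjusted p up to 0.00109, 0.00304, 0.00304, 0.0173 and 0.0256. Over 4076 comparisons of a named gene with another setting, 3771 kept their side of the threshold without a called change of direction (78 of them uncalled with the opposite sign), 235 lost and 69 gained a call, and 1 reversed. Beside single genes the report gives calls lost with 1 library left out, and losses under other settings only where stated. The 1050 calls became 1622 with DESeq2 (661 lower), 375 at an adjusted p under 0.01 (276 higher, 99 lower), 334 with a fold change of at least 2 (247 higher, 87 lower) and 656 without control replicates 1 and 2 (194 lower), and with embryo sex as a covariate 245 were lower. Leaving out 1 library gave 636 (without control replicate 2) to 1025 (without control replicate 3) calls, 430 (without p53_activated replicate 5) to 707 (without p53_activated replicate 1) higher and 192 (without control replicate 2) to 433 (without control replicate 3) lower. For Trp53 the log2 fold change was 0.562 to 0.804 with 1 library left out, 0.483 without control replicates 1 and 2 and 0.648 without p53_activated replicates 4 and 5, the last 2 no longer called (adjusted p 0.107 and 0.0861). Fewer libraries leave less power, and otherwise the cause was not tested.

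Calls of the smaller list shifts were lost as follows (adjusted p). With an estimated correlation the values were 0.603 for G2 and mitosis, 0.635 for G1/S, 0.635 for neuroepithelium, 0.635 for epithelium, 0.615 for muscle and somite, 0.603 for stress response and 0.775 for ribosomal proteins, and with fry 0.115, 0.222, 0.278, 0.273, 0.222, 0.167 and 0.314. The globin ratio as covariate gave 0.0519 for G2 and mitosis, 0.246 for G1/S, 0.239 for neuroepithelium and 0.246 for ribosomal proteins. Without control replicates 1 and 2 these were 0.106, 0.699, 0.599 and 0.6, and stress response was 0.0958. Without p53_activated replicates 4 and 5 neuroepithelium was 0.0677. The epithelial score as covariate gave 0.195 for neuroepithelium, 0.283 for muscle and somite and 0.251 for ribosomal proteins, and reversed epithelium (0.942, by construction), the erythroid list (0.0351) and Hbb-bh1 (log2 fold change 1.05). Ribosomal proteins were at 0.105 with sex as covariate. Leaving out 1 library gave 0.00203 to 0.165 for G1/S, 0.00129 to 0.171 for neuroepithelium, 0.0018 to 0.0888 for stress response and 0.00119 to 0.198 for ribosomal proteins. Calls were gained for the arch list (higher, 0.0158) and the Hox list (lower, 0.0209) without control replicates 1 and 2, for the erythroid list without p53_activated replicates 4 and 5 (lower, 0.000152) and for the endothelial list with the epithelial score as covariate (higher, 0.0323). The cause of these losses and gains was not tested.

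The replicate numbers share no stated litter or day. Libraries of the same number had correlated deviations of -0.053 to 0.113, above 0.1 for 1 of 5 numbers. For 0 numbers were they each other's best match, so deviations over all tested genes did not pair the embryos. The epithelial score was higher in control replicates 4 and 5 (1.3 and 1.445) than in control replicates 1 to 3 (-0.272 to 0.016). The same held in p53_activated (0.732 and 0.102 against -1.708 to -0.701). The erythroid score was lowest in replicate 3 (-1.342 and -2) and highest in replicate 4 (1.042 and 1.523) of both groups. A litter or day shared by number therefore stays open. With the replicate block 804 genes were called, 727 of them among the 1050, the ribosomal list was no longer called (0.085) and the erythroid list was called lower (0.0212). Of 77 named calls 11 were lost with the block and 8 further named genes gained one.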

Other observations

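The lists in the first 2 paragraphs, the tests of stage, other tissue and power, and the count of other splits were chosen only after the results were seen. Genes of synaptic vesicles and secretory granules were lower in p53_activated embryos. Of 25 tested, 10 fell and none rose (16 fell adjusted over the list alone), with a median log2 fold change of -0.77 (camera adjusted p = 5.65e-12; adjusted p = 0.19 with an estimated correlation). Their centred mean log2 CPM was 0.749 and 0.67 in control replicates 1 and 2 (0.098 to 0.3 in the other controls) and -0.098 and -0.18 in p53_activated replicates 4 and 5 (-0.586 to -0.563 in the other 3). Without control replicates 1 and 2 the median was -0.59 and 6 were called lower, and without p53_activated replicates 4 and 5 it was -0.96 and 12 were. Scg3 (-0.95 ± 0.13) and Chga (-0.82 ± 0.15), which act in granule formation, and the vesicle protein gene Syp (-0.77 ± 0.15) were among them. Of 8 noradrenergic genes Cyb561 fell (1 adjusted over the list alone; camera adjusted p = 0.0241; adjusted p = 0.19 with an estimated correlation). Of 15 cholesterol synthesis genes the enzyme genes Hmgcs1 (-0.56 ± 0.10) and Cyp51 (-0.43 ± 0.08) fell and none rose (8 lower and 1 higher adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.00189; adjusted p = 0.407 with an estimated correlation).

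Of 14 Notch pathway genes 4 rose and none fell (5 rose adjusted over the list alone; camera adjusted p = 0.0708), namely the receptor genes Notch3 (1.69 ± 0.33), Notch1 (1.94 ± 0.44) and Notch2 (0.59 ± 0.17) and the ligand gene Jag2 (1.22 ± 0.33). Notch1 was 62.59 and 52.72 CPM in p53_activated replicates 4 and 5 and 5.743 to 26.38 in the other 8 libraries, and lost its call without control replicate 1 (0.0793), 2 (0.0697), 3 (0.0504) or 4 (0.0704) or p53_activated replicate 5 (0.0539). Notch2 lost its call without each library but control replicate 1 and p53_activated replicates 1 and 2 (up to 0.0955), and Jag2 without control replicates 2, 3 and 4 or p53_activated replicates 3, 4 and 5 in turn (up to 0.0929). Among 20 guidance genes Plxna1 rose (1.57 ± 0.27) and the neuropilin gene Nrp1 fell (-0.69 ± 0.13; 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.943). Among 14 BMP and Wnt response genes Axin2 rose (0.94 ± 0.20) and Lef1 fell (-0.68 ± 0.18; 1 each adjusted over the list alone; camera adjusted p = 0.533), Lef1 losing its call without each library but control replicates 3 and 4 and p53_activated replicate 4 (up to 0.0799). Among 7 stage-dependent genes Igf2bp1 rose (0.37 ± 0.10; 1 adjusted over the list alone; camera adjusted p = 0.187), a call lost without each library but control replicates 3 and 4 and p53_activated replicate 1 (up to 0.108). Of 8 antigen processing genes Tap1 rose (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.533), and of 14 glycolysis and hypoxia genes 0 were called at either adjustment (camera adjusted p = 0.943). Without p53_activated replicates 4 and 5 calls were lost for Axin2 (0.58, adjusted p = 0.0547), Jag2 (0.75, 0.247), Notch2 (0.34, 0.196), Lef1 (-0.72, 0.0869) and Igf2bp1 (0.39, 0.0998). Without control replicates 1 and 2 they were lost for Lef1 (-0.37, 0.152), Igf2bp1 (0.23, 0.159), Jag2 (1.22, 0.103), Notch1 (1.78, 0.168), Notch3 (1.81, 0.097) and Plxna1 (1.64, 0.0722). With the gene length trend removed they were lost for Notch2 (0.44, 0.0529) and Igf2bp1 (0.25, 0.224).

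Markers of neurons, glia and melanoblasts were lower in p53_activated embryos. Without control replicates 1 and 2 every p53_activated library still lay at least 0.398 (log2) below the remaining controls, with median globin ratios of 1.95 and 1.94, which argues against an earlier stage of the whole embryos as far as that ratio tells stage. With the epithelial score as a covariate 15 of the 31 markers were still called lower. Their median log2 fold change was -0.779 with the score and -0.855 without it. This argues against less epithelial tissue as the whole cause, while other tissues are not covered by that score. An equal loss of every neuronal transcript is argued against by the spread of the members (exact permutation over 252 assignments, p = 0.00794, the smallest they can give). Fewer cells and lower expression per cell were not separated, and the explanation is left open.

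Higher calls were more frequent among long genes and lower calls among short genes. Greater power for long genes would make both kinds of call more frequent there. Lower calls were less frequent in the longest eighth (19 against 60, Fisher's exact test, two-sided, p = 3.31e-06, with genes counted as independent). The direction of these counts, rather than that p, argues against power as the whole explanation. With the gene length trend removed both kinds were more frequent in the longest than in the shortest eighth (107 against 28 higher, 55 against 34 lower), as greater power would give, so it may add to the pattern. The correlation across genes of log2 fold change with log2 exon length was 0.143 with all libraries and 0.051 without p53_activated replicates 4 and 5. Genes are not independent replicates, and this value lies between the bounds set for and against those libraries as the source. A length trend in these libraries and an effect of p53 on long genes therefore cannot be told apart. Per library, the slope of log2 CPM, relative to the mean of all libraries, on log2 exon length was -0.0555 to -0.0027 in the controls. It was 0.1269 and 0.0481 in p53_activated replicates 4 and 5, but -0.0242, 0.0066 and -0.0126 in p53_activated replicates 1, 2 and 3. Replicates 1 and 3 thus lay within the range of the controls.

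Of 100 splits drawn from the 126 ways to divide the libraries into groups of 5, only 1, the real one, gave as many called genes (1050). The highest of the others gave 7. Every other split mixed the genotypes, so a genotype difference would add to the spread within its groups and lower its calls. A share of 1 in 100 is the smallest these splits can give, and it argues against chance for the count without excluding it.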
